A study of Homo sapiens with 6 samples.

How the data were processed

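RNA was measured in 6 libraries of engineered cardiac tissue, 3 without and 3 with iM0, at day 28. Per the labels' protocols, frozen tissues were homogenised, RNA with an integrity number above 8 was accepted, and libraries were made with a Nextera XT kit from 100 to 150 pg of material. Whether the libraries keep strand is not given in the sources used here, so a gene and an overlapping antisense gene cannot be told apart. Such small inputs are amplified, and reads carry no molecular identifiers, so floors cover counting error only. Per the submitters' processing notes, bcl2fastq 2.19 and kallisto 0.44.0 were used with the genome build GRCh38.p12. The authors deposited a gene table of estimated counts and a gene table of TPM, with 36459 gene symbols each, and a kallisto transcript table per library with 188753 transcripts. The deposited estimated counts of genes are whole numbers and were used as they stand, so rounding changed nothing. Groups were taken from the sample labels, and all columns of the gene tables belonged to these 6 libraries.

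Transcript estimates were summed per symbol with GENCODE 29 and lay within 1 count of the deposited gene table for 96.3% to 96.4% of 35266 symbols. Transcripts with no symbol in that release held 2.38% to 2.44% of counts. Gene positions are from the same release, on GRCh38. Fragment length was taken as the mean of length minus effective length over transcripts longer than 3000 bases. Replicates were checked against sampling noise: a chi-square statistic per degree of freedom lay between 23.9 and 32.6 for pairs within a group, so no pair looked like one library deposited a second time.

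The test of each gene was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, robust fit) on the estimated counts, with TMM factors and the default expression filter (minimum count 10, minimum total 15), which kept 17635 genes. Calls had a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were the fold change divided by the square root of F. In total 36 gene lists, chosen before the data were examined, were tested with limma 3.58.1 camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2, and again with an estimated correlation and with fry. Of 899 list members, 894 were found in the table, 1 of them by an older symbol, and 837 were tested; the others were not analysed here. Summed TPM per library was compared by exact two-sided permutation, whose smallest p for 3 against 3 is 0.1. Where all libraries of a group had 0 counts, the fold was taken against 3 counts over the group.

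Named genes followed a rule set before the data were examined: the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM above 1 whose groups did not overlap in TPM, up to 3 called members of each list with the smallest p (or 2 of highest expression where none was called), and CSF1R, CD68, CD14, PTPRC, ADRB1, TNNT2, MYH6, MYH7, RYR2, ATP2A2, COL1A1 and COL3A1. Clone-based names were counted but not named, and some genes that met the rule are not reported here. Other genes named in the text are said to have been chosen after their values were seen. Among 2096 called genes with at least 1 TPM in both groups, the TPM ratio lay within 0.5 of the fitted log2 fold change for 1962 and over 1 away for 47. For 10 of the 2096 the TPM ratio had the opposite sign.

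The test was tried on simulated counts for 17635 genes with 200 changed. With gene-wise dispersions as estimated from the data, it recovered 54% of 1.5-fold, 74% of 2-fold, 86% of 4-fold and 92% of 8-fold changes, and 29 of 182 calls were false (15.9%), above the nominal rate. With dispersions from the trend, 5 of 162 calls were false (3.09%). With no change simulated, 3 genes were called and 4.88% had p under 0.05. The false rate with gene-wise dispersions means that calls close to the threshold are less sure than their adjusted p states. For camera, a list of 30 genes raised 1.5-fold was called and none of 20 random lists was. Genes were simulated independently of each other. In the data the estimated correlation was 0.726 in the mitochondrially encoded list and 0.409 in the fibroblast and collagen list. The simulation therefore cannot give the false call rate of camera at the preset correlation of 0.01. A correction for transcript length and GC content, a loess trend per library (span 0.4) passed to edgeR as offsets, was also tried on simulated data: a simulated trend gave 2355 false calls without and 6 with the correction, and 160 of 200 changed genes were recovered with it.

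Alternatives were other scaling factors (RLE, upper-quartile, none), no or a stricter low-count filter, DESeq2 1.42.0, limma-voom without and with quality weights, limma on log2(TPM + 1) and log2(TPM + 0.1), length-scaled transcript sums, other thresholds and leaving out each library in turn. All were chosen before the data were examined.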

Results

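Bulk RNA sequencing compared human engineered cardiac tissues built with and without macrophages. The tissues held cardiomyocytes and cardiac fibroblasts made from induced pluripotent stem cells of the WTC11 line, a human reference line, set in a fibrin gel between flexible pillars. In one group, macrophages made from the same stem cell line (iM0) were mixed in when the tissue was formed. Each group had 3 libraries, taken at day 28. All tissues had received electromechanical stimulation from day 7 for 2 weeks and were then paced at 2 Hz. The labels do not say whether the 3 tissues of a group came from separate differentiations, so p-values measure the spread between these samples, which may be partly technical. Libraries without iM0 held 46310169, 47041891 and 49937694 estimated counts, and libraries with iM0 held 41946805, 50866280 and 49799239. At these depths 3 counts correspond to between 0.0590 and 0.0715 CPM (counts scaled to library size) in one library. The mean sequenced fragment, read from the transcript tables, was 299.3, 302.2 and 303.8 bases long without iM0 and 297.1, 285.6 and 269.5 bases long with iM0. Spearman correlation between libraries lay between 0.990 and 0.992 within groups and between 0.948 and 0.954 across groups. The first principal component of the 500 most variable genes separated the groups and held 93.0% of their variance.

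The comparison asked which transcripts differed when macrophages had been part of the tissue from its formation. Macrophage genes were the largest rises, 25 of 39 collagen and other matrix genes rose and 2 fell, sarcomere genes stayed close to their level as a list, and MYH6, ID1 and ID4 were among the largest falls. Of 17635 genes tested, 2794 changed, of which 1935 rose and 859 fell with iM0. Rises were also larger: 1140 genes rose at least 2-fold and 126 fell at least 2-fold. The median rise was 1.33 on the log2 scale and the median fall had a size of 0.53. The 1935 risen genes included 473 with a mean below 0.5 TPM (abundance scaled for transcript length and library size) without iM0, and 941 with at least 5 TPM there. In 35.7% of tested genes the 3 libraries of one group all lay above those of the other in TPM, where chance gives 10%. That share includes genes that were not called, such as TNNT2, and part of it may come from the shift of the TPM scale given below. The split between rises and falls moved with the scaling: 69.3% of calls rose with TMM factors, 58.4% with upper-quartile factors and 52.8% with library size alone. It was 45.6% with limma on log2(TPM + 1) and 45.7% on log2(TPM + 0.1), which change the test, the unit and the gene filter together. The median log2 fold change of all genes analysed lay at -0.01 with TMM factors, -0.09 with library size alone, -0.12 on the log2(TPM + 1) scale and -0.13 on the log2(TPM + 0.1) scale, so fold changes below are relative to the TMM scale.

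The 10 named genes with the largest fitted rise had no count in any library without iM0. These were C1QA, C1QB and C1QC, the chains of complement C1q, and F13A1, ADAMDEC1, PLEK, HLA-DRA, FOLR2, SLAMF8 and APOC2. Against a floor of 3 counts over the 3 libraries, C1QB was at least 13690-fold higher, F13A1, which encodes a subunit of coagulation factor XIII, at least 13540-fold and C1QA at least 10850-fold. C1QB reached 469 ± 68.9 TPM (SD, n = 3) with iM0. Of 32 tested genes of macrophage identity, 31 rose and none fell, and 31 rose when adjusted over the list alone. CSF1R, the receptor for macrophage colony-stimulating factor, on chromosome 5 from 150053291 to 150113372 in GRCh38, went from 0.995 ± 0.380 to 27.6 ± 3.76 TPM (SD, n = 3), and the fit to counts gave a larger log2 fold change of 7.09 ± 0.19 (SE, adjusted p = 2.64e-11). CD68, a lysosomal glycoprotein of macrophages, went from 0.803 ± 0.436 to 192 ± 8.54 TPM (SD, n = 3). CD14 rose by 7.71 ± 0.22 and PTPRC, the pan-leukocyte antigen CD45, by 4.65 ± 0.13 on the log2 scale in counts, with PTPRC at 2.47 ± 0.122 and 25.7 ± 3.89 TPM (SD, n = 3). CX3CR1 was the member that did not pass. The list median was 8.10 on the log2 scale, and 8.05 with the members that had no counts set at their bound. Fold changes from counts and from TPM differed for several genes, which leaves their size less certain. For CSF1R, PTPRC, CD163, MSR1, PECAM1, ALDH1A2, CD14, CD74, GPNMB, ADCY3 and ADCY7 the TPM ratio was smaller by over 0.5 on the log2 scale, and for IGF1 it was larger by over 0.5. For CD163, the fitted log2 fold change of 3.91 from counts stood beside TPM of 12.2 ± 1.15 and 21.5 ± 1.13 (SD, n = 3).

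**Figure D1:**
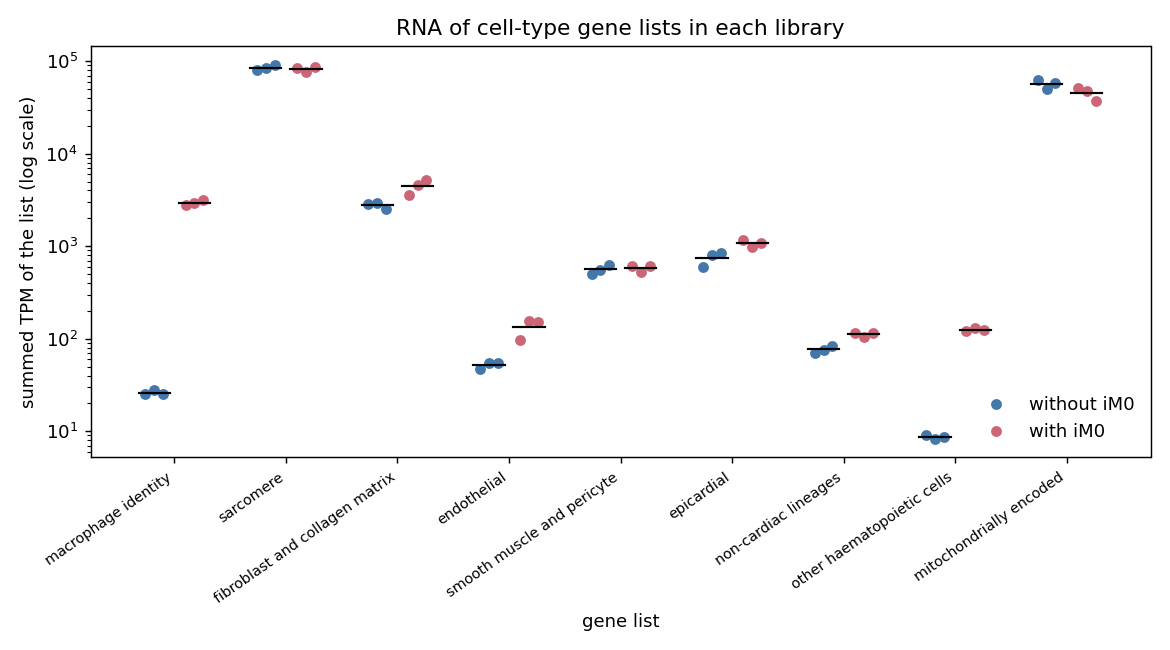
Summed TPM (log scale) of 9 gene lists in each of the 6 libraries, with points for libraries and black lines for group means. Macrophage identity genes summed to 26.2 TPM on average without iM0 and 2963 TPM with iM0, while sarcomere genes summed to 85333 and 82461 TPM.

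Genes of several macrophage functions rose together. Macrophages were added to one group only, so rises of genes that macrophages express follow from the design. The lists also share members, such as CD163, F13A1 and TREM2, so their calls are not independent and do not separate macrophage states. All 29 tested lysosomal genes rose, among them the cathepsin CTSH by 4.34 ± 0.12 and GPNMB by 8.64 ± 0.12 on the log2 scale. All 17 tested genes of lipid-associated and osteoclast-like macrophages rose, with a median of 8.30, or 7.86 with members at 0 counts at their bound. SPP1, which encodes osteopontin, went from 1.10 ± 0.260 to 1599 ± 186 TPM (SD, n = 3). Of 11 MHC class II genes, 10 rose, and CD74, the invariant chain, rose by 9.16 ± 0.14. Reads of the HLA genes can be shared between family members, which leaves their individual values uncertain. Of 20 pro-inflammatory cytokine genes, 17 rose, among them CCL4, at least 923-fold higher. Of 13 genes of alternatively activated macrophages, 9 rose, among them MSR1 by 4.79 ± 0.17 in counts, beside TPM of 5.28 ± 0.270 and 17.7 ± 1.53 (SD, n = 3). Resident-like cardiac macrophage genes rose in 10 of 13 cases, and SELENOP, a selenium carrier, went from 100 ± 9.92 to 547 ± 31.6 TPM (SD, n = 3). Complement genes rose in 17 of 21 cases, while C4A fell by 0.56, a member named after its values were seen that shares reads with C4B. Phagocytosis genes rose in 11 of 21 cases, with TREM2 at least 1116-fold higher. All these lists passed camera, with adjusted p between 1.95e-48 for macrophage identity and 1.58e-08 for phagocytosis. With an estimated correlation, macrophage identity (adjusted p = 0.0221), MHC class II (adjusted p = 0.0240), lysosome (adjusted p = 0.0388), lipid-associated (adjusted p = 0.0240) and alternatively activated genes (adjusted p = 0.0364) still passed. Resident-like (adjusted p = 0.0544), complement (adjusted p = 0.0651), phagocytosis (adjusted p = 0.0544) and cytokine genes (adjusted p = 0.0638 with an estimated correlation) did not.

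Matrix genes of fibroblasts were higher with iM0. Of 39 tested members of the fibroblast and collagen list, 25 rose and 2 fell, and 27 rose and 3 fell when adjusted over the list alone. COL1A1, a chain of type I collagen, went from 117 ± 17.7 to 401 ± 122 TPM (SD, n = 3), which was 3.90-fold higher in the fit (adjusted p = 5.28e-04). COL3A1 of type III collagen rose by 2.00 ± 0.20 (SE, adjusted p = 1.74e-04), COL6A2 by 1.44 ± 0.12 and LOXL2, a collagen crosslinking enzyme, by 1.25 ± 0.12. VCAN, the proteoglycan versican, went the other way and fell by 1.30 ± 0.11 (SE, adjusted p = 2.59e-06), as did COL14A1, named after its values were seen, by 0.49. The list sum was 2775 ± 220 TPM without iM0 and 4443 ± 797 TPM with iM0 (SD, n = 3), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. The list passed camera (adjusted p = 8.14e-12) and did not with an estimated correlation (adjusted p = 0.2). Of 24 matrix-degrading enzymes and inhibitors, 13 rose and ADAMTS5, named after its values were seen, fell by 1.29. MMP12, with 0 counts without iM0, was at least 1098-fold higher, and MMP9 rose by 8.04 ± 0.25. The list passed camera (adjusted p = 1.16e-07), also with an estimated correlation (adjusted p = 0.0338). Bulk RNA cannot assign the rises of this list to fibroblasts or to the added macrophages. The myofibroblast list had 7 rises and 2 falls of 18 (camera adjusted p = 0.0318, and adjusted p = 0.172 with an estimated correlation). The call of this list was also lost without without_iM0 replicate 3 (adjusted p = 0.0656), without with_iM0 replicate 1 (adjusted p = 0.0842) and without with_iM0 replicate 3 (adjusted p = 0.0562). After a correction for transcript length and GC content, possible for 16 of the 18 members, it was lost too (adjusted p = 0.202), although the median of these 16 was 0.32 before and 0.33 after (bootstrap SE 0.153) and 8 of them were called before and after; the cause was not tested.

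Sarcomere genes did not move together. Of 30 tested members, 3 rose and 2 fell, and the list did not pass camera (adjusted p = 0.841). Their summed level was 85333 ± 5858 TPM without and 82461 ± 5794 TPM with iM0 (SD, n = 3, exact two-sided permutation p = 0.6). The list median was 0.02 with TMM factors and -0.09 on the log2(TPM + 1) scale. MYH6, the alpha myosin heavy chain, went from 670 ± 148 to 221 ± 34.2 TPM (SD, n = 3) and fell by 1.52 ± 0.14 on the log2 scale (SE, adjusted p = 2.23e-05). MYH7, the beta chain, lies beside it on chromosome 14 and had a log2 fold change of 0.00 ± 0.14 (SE, adjusted p = 0.996), with 2781 ± 516 and 2590 ± 379 TPM (SD, n = 3). The pair are close paralogs, so reads can be shared between them. TNNT2, cardiac troponin T, had a log2 fold change of -0.12 ± 0.10 (SE, adjusted p = 0.486), and on the log2(TPM + 1) scale of -0.24 (adjusted p = 0.0153). TNNI3, the adult cardiac troponin I, rose by 0.86 ± 0.18 (SE, adjusted p = 0.0157), and its call was lost without with_iM0 replicate 1 (adjusted p = 0.0724) or without_iM0 replicate 1 (adjusted p = 0.0816), and with no low-count filter (adjusted p = 0.1). XIRP1 rose by 0.41 ± 0.10 and lost its call without with_iM0 replicate 3 (adjusted p = 0.0714). CSRP3 rose by 0.55 and MYPN fell by 0.47, both named after their values were seen.

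**Figure D2:**
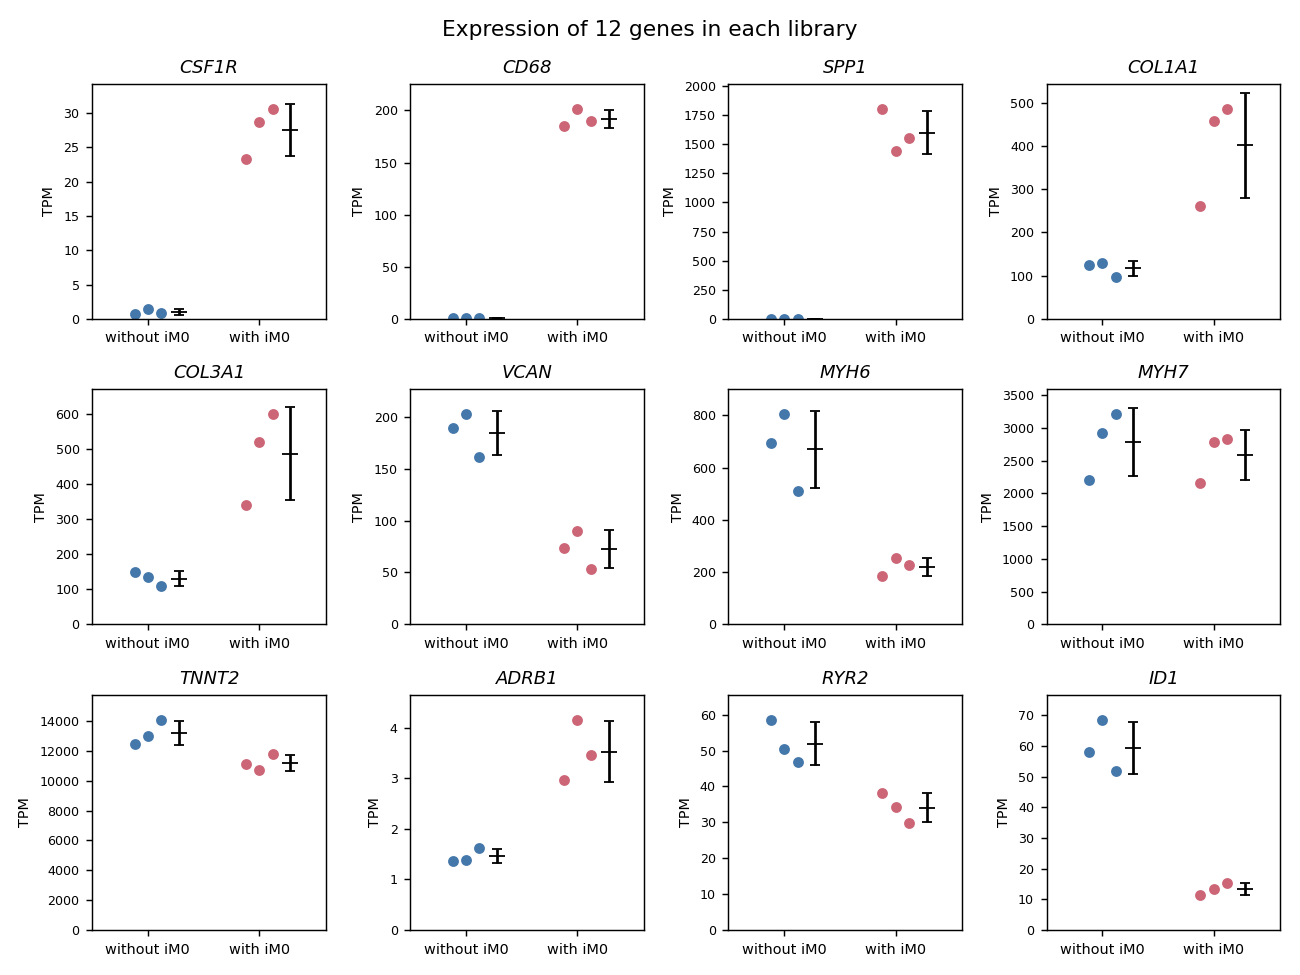
TPM of 12 genes in each library (points), with the group mean and SD (black bars, n = 3). The 3 libraries with iM0 lie above the 3 without for COL1A1 and ADRB1 and below them for MYH6, VCAN, RYR2 and ID1, whereas MYH7 overlaps.

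Most genes of excitation and calcium cycling did not pass the threshold. Of 30 cardiac ion channel genes, none rose and 5 fell, with a list median of -0.17 (camera adjusted p = 0.00874, and adjusted p = 0.0880 with an estimated correlation). CACNA1D, an L-type calcium channel, fell by 0.98 ± 0.15, and KCND3 and KCNJ8, named after their values were seen, fell by 0.92 and 0.43. HCN4, a pacemaker channel, fell by 0.38 ± 0.10 and lost its call when any one library other than without_iM0 replicate 3 was left out, with adjusted p from 0.0502 to 0.104. Calcium handling genes had 2 rises and 6 falls among 27 and did not pass as a list (adjusted p = 0.0679), although they did with library size alone (adjusted p = 0.0318), with a stricter low-count filter (adjusted p = 0.0413) and without without_iM0 replicate 1 (adjusted p = 0.0259). RYR2, the calcium release channel of the sarcoplasmic reticulum, fell by 0.39 ± 0.09 (SE, adjusted p = 0.00746) and CACNB2 by 0.54 ± 0.09. ATP2A2, the calcium pump SERCA2, had a log2 fold change of -0.29 ± 0.10 (SE, adjusted p = 0.0720), and passed in 8 alternatives with adjusted p from 0.0199 to 0.0486. Beta-adrenergic and cAMP genes had 8 rises and 4 falls of 33 (adjusted p = 0.591). ADRB1, the beta-1 adrenergic receptor, went from 1.46 ± 0.14 to 3.53 ± 0.601 TPM (SD, n = 3) and rose by 1.38 ± 0.21 (SE, adjusted p = 4.44e-04). The adenylyl cyclases ADCY3 and ADCY7 rose by 2.43 ± 0.20 and 2.38 ± 0.20. Bulk RNA cannot assign these rises to cardiomyocytes, fibroblasts or the added macrophages.

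The following lists of cardiomyocyte state and metabolism did not pass: mature cardiomyocyte (3 rises and 3 falls of 24, adjusted p = 0.575), fetal or immature cardiomyocyte (1 rise and 3 falls of 20, adjusted p = 0.730), intercalated disc (1 rise and 2 falls of 19, adjusted p = 0.323), nuclear oxidative phosphorylation (1 rise of 52, adjusted p = 0.825), fatty acid oxidation (3 rises and 2 falls of 30, adjusted p = 0.773) and glycolysis (3 rises and 5 falls of 25, adjusted p = 0.516). Within them CKM, muscle creatine kinase, fell by 0.63 ± 0.08 and MB, myoglobin, by 0.39 ± 0.07, while CD36, a fatty acid transporter that macrophages also express, rose by 1.72 ± 0.15. ANK2 of the intercalated disc list fell by 0.49 ± 0.13. Its call was lost when any 1 library other than with_iM0 replicate 2 was left out (adjusted p from 0.0513 to 0.102). Mitochondrially encoded transcripts made up 5.73 ± 0.653% of TPM without and 4.52 ± 0.749% with iM0 (SD, n = 3, exact two-sided permutation p = 0.2). Their list passed camera downward (adjusted p = 0.0111) with 1 of 13 members, MT-ATP8, past the threshold (adjusted p = 0.0172, and from 0.0611 to 0.0780 without without_iM0 replicate 1, with_iM0 replicate 1 or with_iM0 replicate 3), and did not with an estimated correlation (adjusted p = 0.587), without without_iM0 replicate 1 (adjusted p = 0.0983) or without with_iM0 replicate 3 (adjusted p = 0.0805). Cytosolic ribosomal protein genes rose slightly, 16 of 56, with a median of 0.20 (camera adjusted p = 6.95e-08, and adjusted p = 0.474 with an estimated correlation).

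Markers of other cell types were measured beside these changes. Endothelial genes rose in 9 of 17 cases (camera adjusted p = 2.00e-09, and adjusted p = 0.115 with an estimated correlation), and their sum went from 52.2 ± 4.17 to 134 ± 32.7 TPM (SD, n = 3). PECAM1 and ENG, which macrophages also express, rose by 5.33 ± 0.21 and 1.95 ± 0.16 in counts, with PECAM1 at 1.08 ± 0.330 and 15.6 ± 2.56 TPM (SD, n = 3), and ESAM, an endothelial adhesion molecule, by 4.43 ± 0.39. Epicardial genes rose in 4 of 11 cases (camera adjusted p = 0.00104, and adjusted p = 0.116 with an estimated correlation), including KRT19 by 0.39 ± 0.08. ALDH1A2 rose by 4.25 in counts but by 0.56 in length-scaled transcript sums, where its call was lost (adjusted p = 0.476). Of 28 other haematopoietic genes only 8 passed the expression filter, and 3 of these 8 rose (camera adjusted p = 0.00891, and adjusted p = 0.105 with an estimated correlation). S100A8, a myeloid calcium-binding protein, rose by 3.13 ± 0.38. S100A9 and RUNX1 were also called, and RUNX1 lost its call with length-scaled transcript sums (adjusted p = 0.263). Bulk RNA cannot assign these rises to the added macrophages or to other blood cells. The smooth muscle list (2 rises and 2 falls of 12, adjusted p = 0.832) and the list of non-cardiac lineages (2 rises of 16, adjusted p = 0.841) did not pass. The non-cardiac list had a median of -0.16 and a mean of 0.15 on the log2 scale, and its sum went from 76.6 to 112 TPM, with APOA1 up by 1.21 ± 0.24 (adjusted p = 0.0590 with no low-count filter).

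Interferon response genes rose in 20 of 30 cases and fell in 2 (camera adjusted p = 4.91e-10, and adjusted p = 0.108 with an estimated correlation). BST2 rose by 2.88 ± 0.16, HLA-E by 2.13 ± 0.09 and B2M, the light chain of MHC class I, by 1.10 ± 0.08, while PSMB9 and TAP1, named after their values were seen, fell by 0.70 and 0.33. Proliferation genes fell in 9 of 23 cases and none rose (camera adjusted p = 3.45e-08, and adjusted p = 0.0638 with an estimated correlation). CCNE2, a cyclin of the start of DNA replication, fell by 0.99 ± 0.15, CENPF by 0.68 ± 0.12 and TOP2A by 0.60 ± 0.13. Apoptosis and p53 genes rose in 7 of 25 cases (camera adjusted p = 0.00220, and adjusted p = 0.0651 with an estimated correlation), and BID rose by 1.51 ± 0.11. Macrophage growth and recruitment signals rose in 5 of 10 cases (camera adjusted p = 0.00497, and adjusted p = 0.0880 with an estimated correlation), with the chemokine CCL2 up by 4.60 ± 0.46, or by 5.27 without without_iM0 replicate 2. Angiogenic factors (5 rises of 18, adjusted p = 0.155), hypoxia genes (6 rises and 2 falls of 23, adjusted p = 0.207) and immediate early and heat shock genes (5 rises and 1 fall of 27, adjusted p = 0.396) did not pass camera. With fry, which asks whether a list's genes move on balance in one direction and makes no comparison with other genes, angiogenic (adjusted p = 3.15e-04), hypoxia (adjusted p = 0.00550) and beta-adrenergic genes (adjusted p = 0.0156) passed upward, while mitochondrially encoded (adjusted p = 0.372) and ribosomal protein genes (adjusted p = 0.0532) did not pass. IGF1, an insulin-like growth factor, rose by 3.04 ± 0.23. Which cells carried the rises in this paragraph, the added macrophages or others, cannot be told from bulk RNA.

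The number of called members changed in many lists when p-values were adjusted over the list alone. Rises then numbered 12 in the resident-like macrophage list, 18 in complement (1 fall), 14 in phagocytosis, 10 in alternatively activated macrophages (1 fall), 4 in other haematopoietic cells, 8 in myofibroblasts (2 falls), 14 in matrix-degrading enzymes (1 fall), 14 in endothelium, 5 in epicardium, 24 in interferon response (2 falls), 9 in apoptosis, 7 in hypoxia (2 falls), 6 in angiogenic factors (1 fall), 6 in immediate early genes (2 falls), 3 in smooth muscle (2 falls) and 26 in ribosomal proteins. Falls adjusted over the list alone numbered 4 in sarcomere (3 rises), 9 in calcium handling (2 rises), 8 in beta-adrenergic signalling (10 rises), 5 in ion channels (1 rise), 3 in intercalated disc (2 rises), 5 in mature cardiomyocyte (3 rises), 6 in glycolysis (3 rises), 13 in proliferation and 0 in nuclear oxidative phosphorylation (0 rises). The counts of the remaining lists were equal either way, apart from the fibroblast and collagen list given above. Median and mean differed in sign from each other or from the direction of camera in 7 lists that did not pass camera: sarcomere, mature cardiomyocyte, fetal cardiomyocyte, nuclear oxidative phosphorylation, glycolysis, smooth muscle and non-cardiac lineages. The median changed sign between scalings in the sarcomere, beta-adrenergic, fetal cardiomyocyte, oxidative phosphorylation, fatty acid oxidation, glycolysis, hypoxia and immediate early lists, none of which passed camera.

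**Figure D3:**
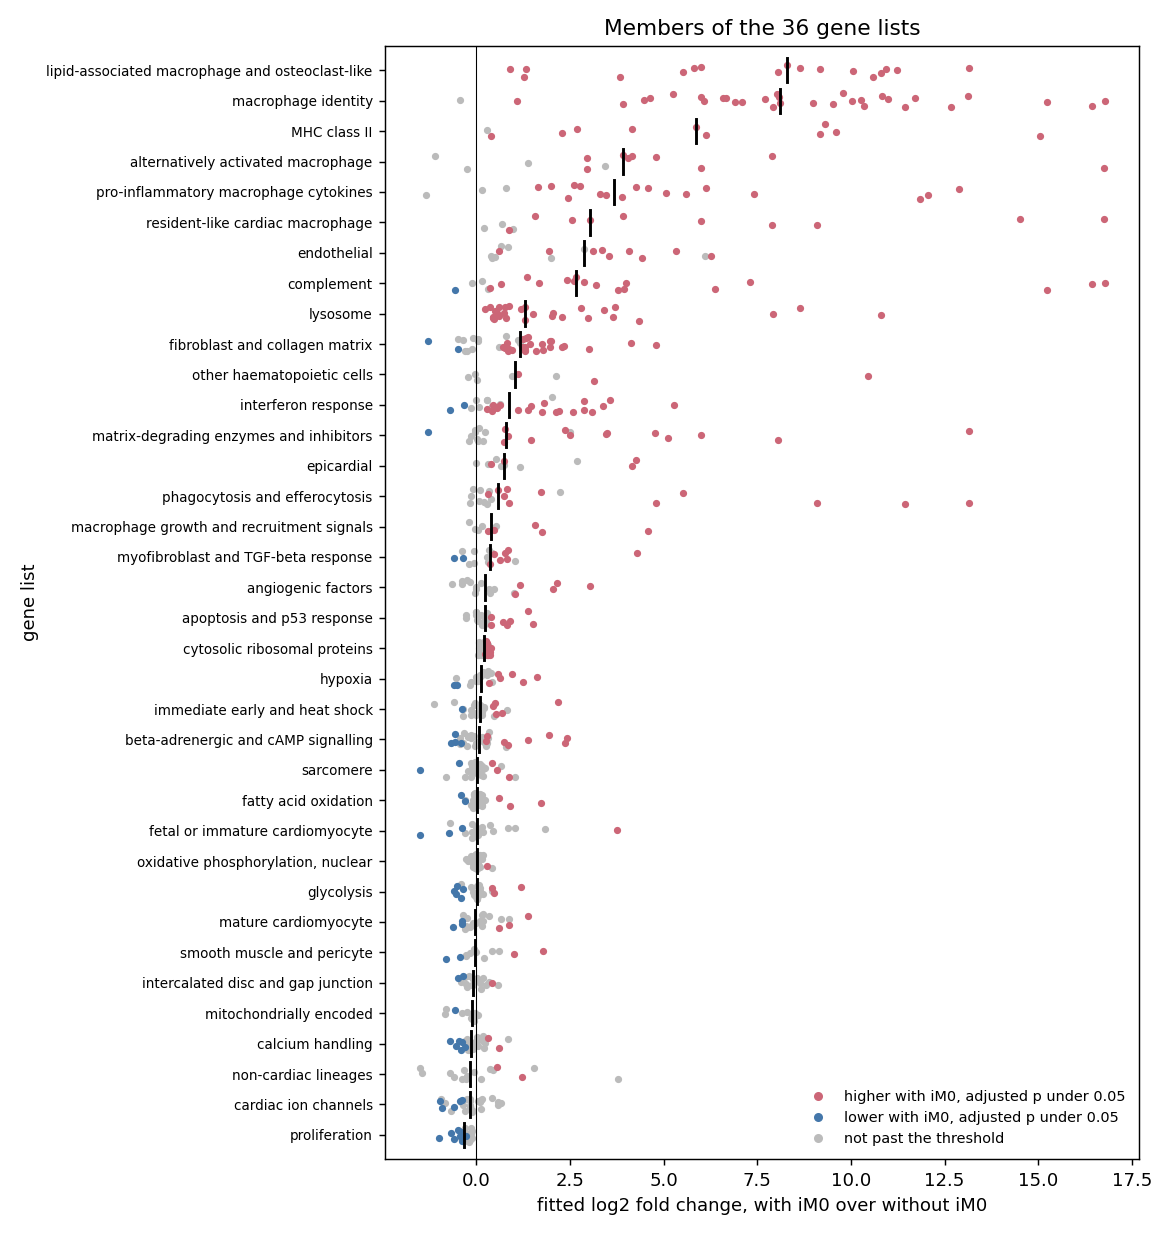
Fitted log2 fold change of each tested member of the 36 gene lists, with iM0 over without iM0, and black lines for list medians. Members of macrophage lists lie farthest to the right, with a median of 8.10 for macrophage identity, and the proliferation list has the lowest median at -0.32. Values of genes with no counts without iM0 depend on the fit and are not bounds.

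Among the genes that met the naming rule, the largest falls were smaller than the largest rises. DNER, a transmembrane ligand of Notch receptors, fell by 2.47 ± 0.19, CRB1, a cell polarity protein, by 2.24 ± 0.22 and TENT5C by 2.15 ± 0.30. ID1, an inhibitor of helix-loop-helix transcription factors on chromosome 20 from 31605283 to 31606515, went from 59.4 ± 8.47 to 13.3 ± 1.99 TPM (SD, n = 3), a fall of 2.03 ± 0.14 (SE, adjusted p = 2.58e-07). ID4 of the same family fell by 1.54 ± 0.14. CNTN5, a contactin of axons, fell by 1.77 ± 0.19, SERTM2 by 1.56 ± 0.29, KIAA0319 by 1.55 ± 0.24 and MYH6 by 1.52. GRIN3A, a glutamate receptor subunit, was 2.84-fold lower and lost its call with length-scaled transcript sums (adjusted p = 0.356). The count of falls moved more with single libraries than the count of rises: it was 523 without without_iM0 replicate 2 and 537 without with_iM0 replicate 3.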

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

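No call shared with the reported test changed sign in any alternative, but not all calls were shared. Of the 2794 calls, 99.43% were kept with DESeq2, 71.73% with length-scaled transcript sums and 63.99% with limma on log2(TPM + 1). Without a filter on TPM 52.22% were kept. Leaving out each library in turn kept 71.15% to 82.21%. Of 119 named genes, 115 were called, and among 2240 recomputed values 2135 kept their side of the threshold, 94 lost the call, 11 gained it and 0 reversed. Most named genes were picked for a large change or a small p in the same data. Their counts therefore do not measure how well calls in general hold. Falls numbered 1488 with library size alone, against 859. With limma on TPM, which changes the unit, the test and the filter together, falls numbered 1424 on log2(TPM + 1) and 1402 on log2(TPM + 0.1). Rises there numbered 1192, 1179 and, without a filter on TPM, 1072, where 1771 genes were called in all. The share of calls that rose was 58.39% with upper-quartile factors, 52.82% with library size alone, 45.57% on log2(TPM + 1) and 45.68% on log2(TPM + 0.1). With an absolute log2 fold change of at least 1 there were 1266 calls, 1140 up and 126 down (90.05% up), and with adjusted p under 0.01 there were 1677 calls, 337 of them down (79.9% up); stricter thresholds leave fewer genes by construction. The cause was not tested for the others. Lists past the threshold fell from 22 to 6 with an estimated correlation. With the stricter low-count filter 1 list lost its call and 1 gained it. The summed level of non-cardiac lineages rose, but its mean log2(TPM + 1) differed by -0.0405. The mitochondrially encoded share differed by -1.22 percentage points of TPM and -0.35 of estimated counts. The first principal component held 72.7% of the variance of all filtered genes. The table held whole numbers, so the alternative without rounding gave no value. No paired analysis was possible because the labels number no replicates across groups.

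Leaving out each library in turn gave 2081 to 2618 calls, 1544 to 1837 rises and 70.17% to 76.36% of calls up. Falls numbered 523 to 781, with 523 without without_iM0 replicate 2 and 537 without with_iM0 replicate 3. Lists called numbered 20 to 22 and risen macrophage identity genes 31 to 32. The log2 ratio of summed TPM ranged from 6.77 to 6.87 for macrophage identity, -0.09 to 0.01 for sarcomere, 0.56 to 0.81 for fibroblast and collagen matrix, 1.23 to 1.54 for endothelial, -0.02 to 0.13 for smooth muscle, 0.40 to 0.63 for epicardial, 0.49 to 0.62 for non-cardiac and 3.81 to 3.88 for other haematopoietic genes. The difference in mitochondrially encoded share ranged from -1.57 to -0.79 percentage points. With 3 libraries per group only 10 splits exist, too few for a share under 0.05. The real split alone called 2794 genes (1 of 10, highest other 0) and 22 lists (1 of 10, highest other 18). Each other split put libraries of both groups on both sides. It therefore held part of the group difference and added that difference to the spread within a side. The counts of the other splits are thus no chance rate, and no conclusion is drawn from them.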

Other observations

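The other ID genes moved with ID1 and ID4. ID2 fell by 1.07 ± 0.09 (SE), from 191 ± 10.5 to 81.4 ± 4.84 TPM (SD, n = 3), and ID3 fell by 1.35 ± 0.10, from 134 ± 16.3 to 47.9 ± 4.63 TPM, both named after their values were seen. These genes encode inhibitors of helix-loop-helix factors and are textbook targets of BMP signalling through SMAD proteins.

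The patterns below were seen in these data before they were tested. The tests of dilution, of reads shared with MYH7 and of lists with members left out were chosen only after the values they use were seen, as was the rule that a list median had to pass its bound by more than its bootstrap standard error. Without that rule the synaptic list would have counted as an exclusion, and with a 95% margin the ion channel test of length and GC content would have stayed open. The bootstrap resampled the genes of a list with the libraries held fixed, so its standard error does not measure spread between tissues.

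A candidate explanation for the ID falls is lower expression of BMP-SMAD targets in general. A list of 24 other genes, ID2 among them and 21 of them tested, was written as BMP-SMAD targets before its values were seen. It also holds the ligands BMP2, BMP4 and BMP7, the receptor BMPR1B and the co-receptor RGMB, so its values are not of targets alone. Of these, BMP7 fell by 0.30 and RGMB by 0.36, while BMP2 rose by 0.95. The list had a median of -0.283 (bootstrap SE 0.0844), short of the -0.3 set in advance, with 7 falls and 2 rises (camera p = 0.00976, and adjusted p = 0.165 with an estimated correlation). SMAD6 fell by 0.69 ± 0.12, whereas HEY2 rose by 0.74 ± 0.13. ID2 belongs to the pattern itself, and without it the median was -0.268 (bootstrap SE 0.0847), with 6 falls and 2 rises among 20 genes (limma camera, p = 0.0363, and p = 0.249 with an estimated correlation). The hypothesis stays open.

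Several genes among the largest falls, DNER, CNTN5, KIAA0319 and GRIN3A, are known from neurons. A hypothesis of lower synaptic and axonal expression was tested on 36 other such genes, and their median was -0.0988 (bootstrap SE 0.130) with 4 falls and 0 rises (limma camera, adjusted p = 0.138). The test gave no evidence for a general fall and its spread is too wide to exclude one.

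The fall of MYH6 was weighed against technical explanations. Dilution by macrophage RNA would lower the other sarcomere genes about as much, but their median was 0.045, and MYH6 lay 2.24 standard errors below the next lowest of them. Bias by transcript length and GC content was argued against, since the log2 fold change after correction was -1.46 ± 0.12 (SE, adjusted p = 3.74e-06). Reads assigned to MYH7 instead remain open: the loss would need MYH7 to rise by 0.20, and the upper 95% bound of its change was 0.275. Lower MYH6 expression in cardiomyocytes of tissues with iM0 therefore also remains open, and explanations other than those named here were not tested.

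The fall of the ion channel list was small. After the correction for length and GC content the median was -0.204 (bootstrap SE 0.0636, camera adjusted p = 0.00465 at the preset correlation; before the correction the call was lost with an estimated correlation, adjusted p = 0.0880), past the -0.10 set in advance by more than its standard error. The correction moved 1620 genes by over 0.1 and left this fall in place, which argues against length and GC bias as its whole cause. Dilution by macrophage RNA could lower all cardiomyocyte genes, and the sarcomere median exceeded the ion channel median by 0.19 with a permutation p of 0.0590. That permutation shuffled list membership across genes and does not measure spread between tissues. It treats genes as independent, although the estimated correlation in the sarcomere list was 0.458. Dilution and a change in cardiomyocytes cannot be told apart, because the spread of 30 small changes is too wide.

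The rise of the collagen matrix list was not removed by the correction for length and GC content (median 1.19, bootstrap SE 0.174). A larger share of fibroblast RNA in tissues with iM0 predicts rises of fibroblast genes outside the list. Of 36 genes written as fibroblast regulators and surface markers, 14 rose and 2 fell. Their median was 0.655 (camera p = 2.47e-06, and adjusted p = 0.132 with an estimated correlation), which met that prediction. The 36 also hold matrix genes, such as COL15A1, COL16A1 and EMILIN1. Their rise therefore cannot separate a larger fibroblast share from higher transcription of matrix genes. Among the regulators and surface markers, PRRX1 rose by 1.335 ± 0.288 and CD248 by 0.95 ± 0.20. OSR1 (0.12 ± 0.12) and PDPN (-0.14 ± 0.09) were not called. Macrophages also express members such as S100A4 and CTSO; without these the median was 0.638 (bootstrap SE 0.154), with 12 rises among 34 genes. A larger fibroblast share may not be the whole cause, since FSTL1, at 568 TPM without iM0, fell by 0.34 ± 0.08, and NID2 and VCAN fell too, and matrix genes transcribed by the macrophages themselves were not tested.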
